A study of Mus musculus with 9 samples.

How the data were processed

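RNA was extracted with TRIzol from monocytes obtained from the spleens of wild-type mice, and sequencing libraries were made with an mRNA kit for Illumina instruments, per the labels' protocols. There were 9 libraries in 3 groups of 3: untreated cells that received the solvent DMSO, cells given a low dose of lipopolysaccharide (LPS, a component of the bacterial outer membrane that Toll-like receptor 4 detects), and cells primed with LPS and then given octanal, an aldehyde that is a ligand of the olfactory receptor Olfr2. The series text gives LPS as 40 ng/ml for 5 hours, octanal as 20 µM for 18 hours and DMSO as a dilution of 1 in 1000. The labels of single samples count up within a group instead, with 18, 19 and 20 hours of octanal and DMSO at 1 in 1000, 1001 and 1002, and all samples of a group were treated as alike here. The labels do not say that LPS samples were kept in culture as long as the octanal samples, so an effect of octanal and of a longer time in culture cannot be told apart here. The sample labels name DMSO for the untreated samples alone, so the solvent may differ between groups as well. They name no sequencing batch and do not say that replicates came from separate animals or cultures, so the p-values measure only the spread between these samples. Replicates of a group differed by a chi-square of 46.5 to 154 per degree of freedom, far above counting error alone. That argues against repeat sequencing of a single library, but the spread may be technical in other ways.

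The authors deposited a count per gene and library, in whole numbers without normalization, per the file headers and the values. The same table holds FPKM values (fragment counts scaled per length and depth), which the authors scaled per gene length and library, per the file headers. The genome build was GRCm38, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here, nor is the use of strand, so reads of overlapping genes and of near-identical copies may be shared between them. The table held 26770 gene rows, of which 22035 carried Ensembl identifiers and 4735 were unannotated loci that the table names NewGene. Of the Ensembl identifiers, 22021 matched the GENCODE M21 annotation of GRCm38, from which positions were taken. There were 10 lines of annotation text without values, which were left out, and 19 entries shared a symbol with another entry and were kept apart by identifier.

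Total counts were 29594291 to 38388421 per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, which lay between 0.923 and 1.07, the filter filterByExpr by group, and the quasi-likelihood test in a single fit of all 9 libraries with a mean per group. The filter left 15447 genes, which held at least 99.9% of each library's counts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and calls with at least a 2-fold change were also counted. Values per group are CPM on TMM-scaled totals, as mean ± SD over 3 libraries, and log2 fold changes come from the edgeR fit with their standard errors. Unless another tool is named, adjusted p of genes are those of edgeR's quasi-likelihood test. With 3 counts taken as the floor over a group, a fold against a group without counts was given as a lower limit, and such limits and the 95% intervals beside ratios of few counts cover counting error only.

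There were 44 gene lists, of pathways and of cell type markers, of which 43 had at least 5 tested members. These were tested with camera from limma 3.58.1, which compares the genes of a list with all other genes, on log2 CPM with a prior count of 3 and a preset correlation between genes of 0.01. List p-values were adjusted over all 129 tests of the 3 comparisons. Each list was also tested with camera using an estimated correlation and with fry. With the estimated correlation a single call held, that of the NF-kappaB list in LPS with octanal against untreated. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 largest rises and the 12 largest falls among called genes with a symbol that is not a predicted gene, at least 10 CPM in the higher group and no overlap between the libraries of both groups. It added Nr4a1 and Dnm1l, genes of the series title, in each comparison, and up to 4 members of lowest p from each list described. Some members that go against the others of their list were named as well.

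The fit was tested on simulated counts for the same 15447 genes with 100 genes changed 2-fold and 100 changed 4-fold. For LPS against untreated, 47 of the 2-fold and 85 of the 4-fold changes were recovered, with 11 false calls. For LPS with octanal against LPS these numbers were 30, 75 and 7, and for LPS with octanal against untreated 50, 81 and 6. In simulations with the NF-kappaB list shifted 1.5-fold, camera called that list in each comparison and 0 of the 42 others. Genes were drawn independently there, so this does not test how camera acts on genes that vary together. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter at a mean of 10 CPM, fits of only the 6 libraries compared, a replicate block, leaving out each library, and limma-trend on log2 of the deposited FPKM plus 1. A fit without the NewGene loci and limma-voom with a sample weight per group were chosen after seeing the data. Comparisons that share a group were set beside 20 simulated data sets with no change in any group.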

Results

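Gene expression was measured by RNA sequencing in spleen-derived mouse monocytes that were left untreated, given LPS, or primed with LPS and then given octanal, with 3 libraries per group. Total counts were 38388421, 29594291 and 30594520 in untreated replicates 1, 2 and 3, 36479579, 31204697 and 34533541 in the LPS replicates, and 34022806, 38229096 and 31938600 in the LPS with octanal replicates. The first principal component of log2 CPM held 48.7% of the variance. On it the untreated libraries scored -104, -34.6 and -68.9, the LPS libraries 65.3, 50.4 and 55.3, and the LPS with octanal libraries 23.7, 15.5 and -2.73. The median SD of a gene's log2 CPM between replicates was 0.31 in the untreated, 0.17 in the LPS and 0.22 in the LPS with octanal group. Transcripts of the mitochondrial genome took 2.85 ± 0.987% of the counts in untreated, 5.36 ± 1.99% in LPS and 2.82 ± 0.443% in LPS with octanal libraries.

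**Figure D1:**
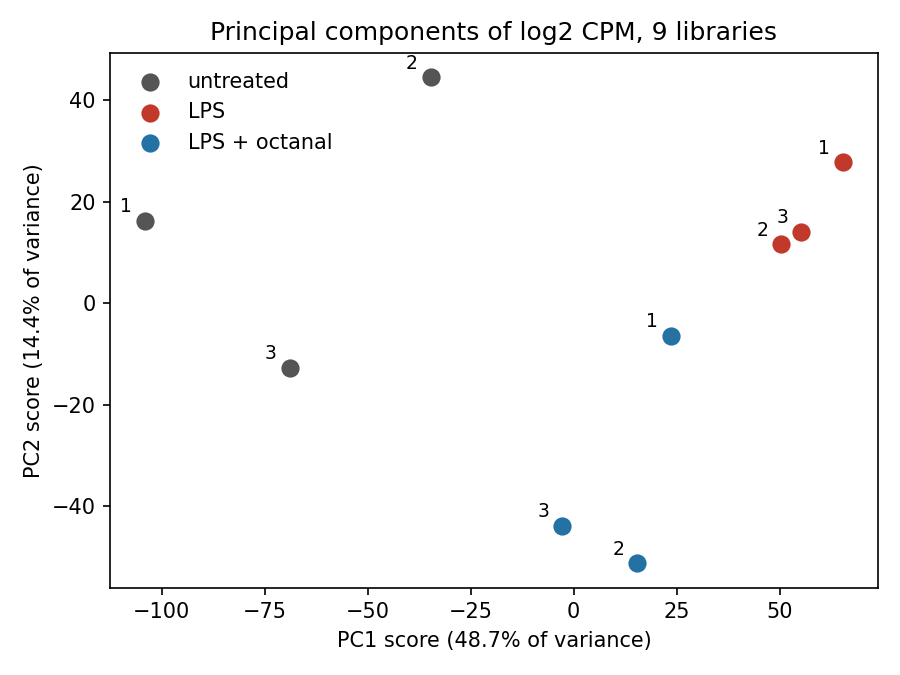
Scores of the 9 libraries on the first principal component (horizontal axis) and the second (vertical axis) of log2 CPM, with a point per library coloured by group and the replicate number beside it. On the first component the LPS with octanal libraries, at 23.7, 15.5 and -2.73, lie between the untreated libraries and the LPS libraries. On the second, with 14.4% of the variance, they lie at -6.38, -51.2 and -43.8. There the untreated libraries lie at 16.2, 44.5 and -12.7 and the LPS libraries at 27.8, 11.6 and 14.1.

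The series title names Nr4a1, an orphan nuclear receptor that is an immediate-early gene, and Drp1, the dynamin-related GTPase of mitochondrial fission that is encoded by Dnm1l. Nr4a1 (ENSMUSG00000023034; GRCm38 chromosome 15, 101254269 to 101274795, protein-coding) stood at 28.0 ± 13.5 CPM in untreated, 31.0 ± 4.79 in LPS and 52.0 ± 13.6 in LPS with octanal libraries. Its log2 fold change was 0.75 (SE 0.343, adjusted p = 0.24) in LPS with octanal against LPS, 0.89 (SE 0.345, adjusted p = 0.14) against untreated and 0.15 (SE 0.343, adjusted p = 0.77) in LPS against untreated. Dnm1l (ENSMUSG00000022789; chromosome 16, 16312230 to 16358959, protein-coding) stood at 80.7 ± 3.35 CPM in untreated and 92.0 ± 7.08 in LPS libraries, and averaged 81.6 (69.3 to 98.3) in LPS with octanal libraries. Its log2 fold changes were 0.19 (adjusted p = 0.29) in LPS against untreated, -0.17 (adjusted p = 0.45) in LPS with octanal against LPS and 0.02 (adjusted p = 0.95) in LPS with octanal against untreated. Neither gene was called with all 9 libraries, but without untreated replicate 2 Nr4a1 passed in LPS with octanal against untreated (1.30, adjusted p = 0.035). The sign of Nr4a1 in LPS against untreated turned without untreated replicate 3 (-0.16) and without LPS replicate 2 (-0.02). That of Dnm1l in LPS with octanal against untreated turned without untreated replicate 2 (-0.03) and without LPS with octanal replicate 1 (-0.13). Olfr2 was not analysed here. The 1190 olfactory receptor genes that were analysed together took 8.80 to 20.3 CPM, on total counts without TMM scaling. Only 33 to 63 of them had a count in a given library.

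LPS against untreated cells asks how these monocytes respond to a low dose of LPS. Whether solvent and time in culture were equal in these groups is not given by the labels. Of the fixed lists, 17 of 24 NF-kappaB pathway genes, 18 of 32 interferon-stimulated genes and 8 of 16 chemokines rose. In turn 14 of 15 neutrophil, 8 of 15 macrophage and 20 of 34 cell cycle genes fell, and with an estimated correlation 0 of 43 lists passed. Cxcl2, which attracts neutrophils, went from 29.9 ± 4.18 to 349 ± 58.8 CPM, a log2 fold change of 3.55 (SE 0.223, adjusted p = 4.1e-04). The granule protein gene Ltf fell from 1798 ± 851 to 11.3 ± 0.849 CPM, a log2 fold change of -7.32 (SE 0.902, adjusted p = 0.0012). Of 15447 genes tested, edgeR called 5072, of which 2353 rose and 2719 fell, and 2465 changed at least 2-fold (888 up and 1577 down).

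The 12 largest rises under the rule were those of the interferon-stimulated genes Oasl1 (log2 fold change 3.68), Ifit1 (3.36), Rtp4 (3.24) and Isg15 (2.57), and of the chemokines Cxcl2, Cxcl1 (3.39), Ccl5 (2.80) and Cxcl10 (2.55). They also held the cytokine Il10 (3.38), the Notch ligand Dll4 (3.17), the receptor F2rl1 (2.75) and the enzyme Carns1 (2.70). Among the 12 largest falls were the granule genes Ltf and Ngp (-6.60), Itgb2l (-6.06), Lrg1 (-6.78), Ifitm6 (-6.40) and the macrophage receptor Trem2 (-5.91). The others were Chil4 (-8.23), Slco4c1 (-7.26), Rab15 (-6.40), Rab44 (-6.22), Pi16 (-5.96) and Amer2. Amer2 had 3148 counts over the untreated and 2 over the LPS libraries, a ratio of 1632 with a 95% counting interval of 451 to 13483. Chil4 has the near-identical copy Chil3, and its value is uncertain for that reason. Without LPS replicate 1, Ifit1 (2.36, adjusted p = 0.082), Rtp4 (2.21, adjusted p = 0.060) and Cxcl10 (2.21, adjusted p = 0.051) were no longer called, and Isg15 went to 1.98. Without untreated replicate 2, Oasl1 went to 4.39, Il10 to 4.36, Ifit1 to 4.47, Rtp4 to 3.89, F2rl1 to 3.66, Carns1 to 3.33 and Cxcl10 to 3.16. Ifit1 and Rtp4 also lost their calls without untreated replicates 1 and 3, and Carns1 did so without each of untreated replicates 1 and 3, the LPS replicates and LPS with octanal replicate 3. Rab15 was not called without untreated replicate 3 (-5.29, adjusted p = 0.065), LPS replicate 2 or LPS replicate 3, and went to -8.75 without LPS replicate 1. Lrg1 went to -6.19 without untreated replicate 1, Chil4 to -7.43 without untreated replicate 3, and Slco4c1 to -6.67 and Trem2 to -6.51 without LPS replicate 1. In LPS libraries Amer2 and Chil4 had counts in replicate 2 alone, and Slco4c1 mostly in replicate 3, so without these their folds rest on a few counts or none.

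Of 24 NF-kappaB pathway genes 17 rose and 0 fell (19 and 0 when adjusted over the list alone), among them Nfkb2 (log2 fold change 0.82), Icam1 (1.13) and Irak3 (1.68). The list was higher by camera (adjusted p = 3.1e-07, adjusted p = 0.15 with an estimated correlation). Of 16 chemokines 8 rose. Ccl6 fell (-3.07). Adjusted over the list alone these counts were 8 and 2 (camera adjusted p = 0.018, adjusted p = 0.45 with an estimated correlation). Of 32 interferon-stimulated genes 18 rose (20 when adjusted over the list alone), with Gbp3 at 2.07 and Gbp5 at 1.69 (camera adjusted p = 1.4e-06, adjusted p = 0.66 with an estimated correlation). LPS replicate 1 stood apart, with a mean centred log2 CPM of 1.61 for this list against -0.02 and 0.39 in LPS replicates 2 and 3. So did LPS with octanal replicate 1, at 1.15 against -0.10 and 0.07 in replicates 2 and 3 of that group. Of 18 MHC class I presentation genes 9 rose, such as H2-Q4 (1.34) and B2m (0.53), and Calr fell (-0.81). The counts were the same when adjusted over the list alone (camera adjusted p = 0.0097, adjusted p = 0.70 with an estimated correlation). Of 45 cytosolic ribosomal protein genes 36 rose (40 when adjusted over the list alone), such as Rplp1 (1.28) and Rps24 (0.93) (camera adjusted p = 1.2e-11, adjusted p = 0.58 with an estimated correlation). The inflammatory cytokine list did not pass (adjusted p = 0.25): 6 of 18 members rose, such as Tnf (1.69), and 3 fell, such as Il18 (-2.43) and the interleukin 1 receptor antagonist gene Il1rn (-0.90).

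Of 15 neutrophil markers 14 fell (14 when adjusted over the list alone), with a median log2 fold change of -4.10 (camera adjusted p = 1.4e-08, adjusted p = 0.45 with an estimated correlation). S100a9, a calcium-binding protein of granulocytes and monocytes, was at 7716 ± 2659 CPM in untreated and 582 ± 99.7 in LPS libraries. Of 6 eosinophil markers 5 fell, such as Prg2 (-4.00) and Siglecf (-3.90), and 5 when adjusted over the list alone (camera adjusted p = 4.4e-04, adjusted p = 0.31 with an estimated correlation). Of 15 macrophage markers 8 fell (9 when adjusted over the list alone), such as Cd68 (-1.96), Apoe (-2.21) and Mertk (-3.02) (camera adjusted p = 0.0023, adjusted p = 0.64 with an estimated correlation). Of 13 classical monocyte markers 8 fell, such as Itgam (-1.93) and F13a1 (-4.59), and 1 rose. These counts were the same when adjusted over the list alone (camera adjusted p = 0.0071, adjusted p = 0.58 with an estimated correlation). In the other direction, all 13 T cell markers rose, such as Lck (1.67) and Cd3g (1.91), also when adjusted over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.65 with an estimated correlation). Of 13 NK cell markers 3 rose, Prf1 (2.19), Nkg7 (1.18) and Klrd1 (1.71), also when adjusted over the list alone (camera adjusted p = 0.0079, adjusted p = 0.58 with an estimated correlation). The share of mitochondrially encoded transcripts was higher in the same LPS libraries, and 4 of 13 such genes rose, such as mt-Atp8 (1.06), also when adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.67 with an estimated correlation). Without LPS replicate 2, which had 7.66% mitochondrial counts, their mean change went from 0.83 to 0.55, and without untreated replicate 1 that of the T cell list went from 2.01 to 1.30. F13a1 went to -3.31 without untreated replicate 1 and to -5.38 without LPS replicate 1, and Klrd1 to 2.42 without untreated replicate 2.

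Of 34 cell cycle genes 20 fell and 0 rose (22 and 0 when adjusted over the list alone), such as Top2a (-3.22) and Ccna2 (-3.35) (camera adjusted p = 1.8e-06, adjusted p = 0.58 with an estimated correlation). Of 23 extracellular matrix and remodelling genes 16 fell, also when adjusted over the list alone, such as Ctsk (-2.94) and Gpnmb (-3.18) (camera adjusted p = 2.9e-07, adjusted p = 0.29 with an estimated correlation). Of 26 fatty acid oxidation genes 13 fell, such as Pparg (-2.66) and Acadl (-1.29). Hadhb rose (0.40). Adjusted over the list alone, 13 fell and 2 rose (camera adjusted p = 2.0e-04, adjusted p = 0.58 with an estimated correlation). Of 76 nuclear genes of oxidative phosphorylation 20 fell (18 when adjusted over the list alone), such as Sdhd (-0.67) and Uqcrb (-0.76) (camera adjusted p = 1.1e-05, adjusted p = 0.70 with an estimated correlation), and without untreated replicate 1 their mean change went from -0.32 to -0.19. Of 15 heat shock genes 5 rose, also when adjusted over the list alone, such as Hspa1a (2.46) and its near-identical copy Hspa1b (1.87) (camera adjusted p = 0.021, adjusted p = 0.68 with an estimated correlation). Of 14 mitochondrial fission genes Fis1 fell (-0.47) and Mief2 rose (0.48), also when adjusted over the list alone, and the list did not pass (adjusted p = 0.74). Of 14 fusion genes Miga1 rose (0.74) and Oma1 fell (-0.54), with 1 and 0 when adjusted over the list alone (camera adjusted p = 0.83). Of 18 mitophagy genes 2 rose, such as Sqstm1 (0.77), and 3 fell, such as Optn (-0.90) and Gabarap (-0.75), also when adjusted over the list alone (camera adjusted p = 0.80). In all, 20 of 43 lists passed with the preset correlation and 0 with an estimated one.

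The number of called genes rested on each LPS library: it was 2387 without LPS replicate 1, 3284 without replicate 2 and 2926 without replicate 3. The 2-fold count was 1520 without LPS replicate 1. Without at least 1 of untreated replicates 1 and 3, the LPS replicates and LPS with octanal replicate 3, the calls of B2m, Cd3g, Lck, Klrd1, Prf1, Nkg7, Hadhb, Hspa1b, Fis1, Mief2, Miga1, Oma1, Sqstm1, Optn and Gabarap were lost. Log2 of the deposited FPKM gave 60.4% of calls as rises, against 46.4% from counts, with the median of the 11493 genes tested in both shifted by 0.11 on the log2 scale.

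**Figure D2:**
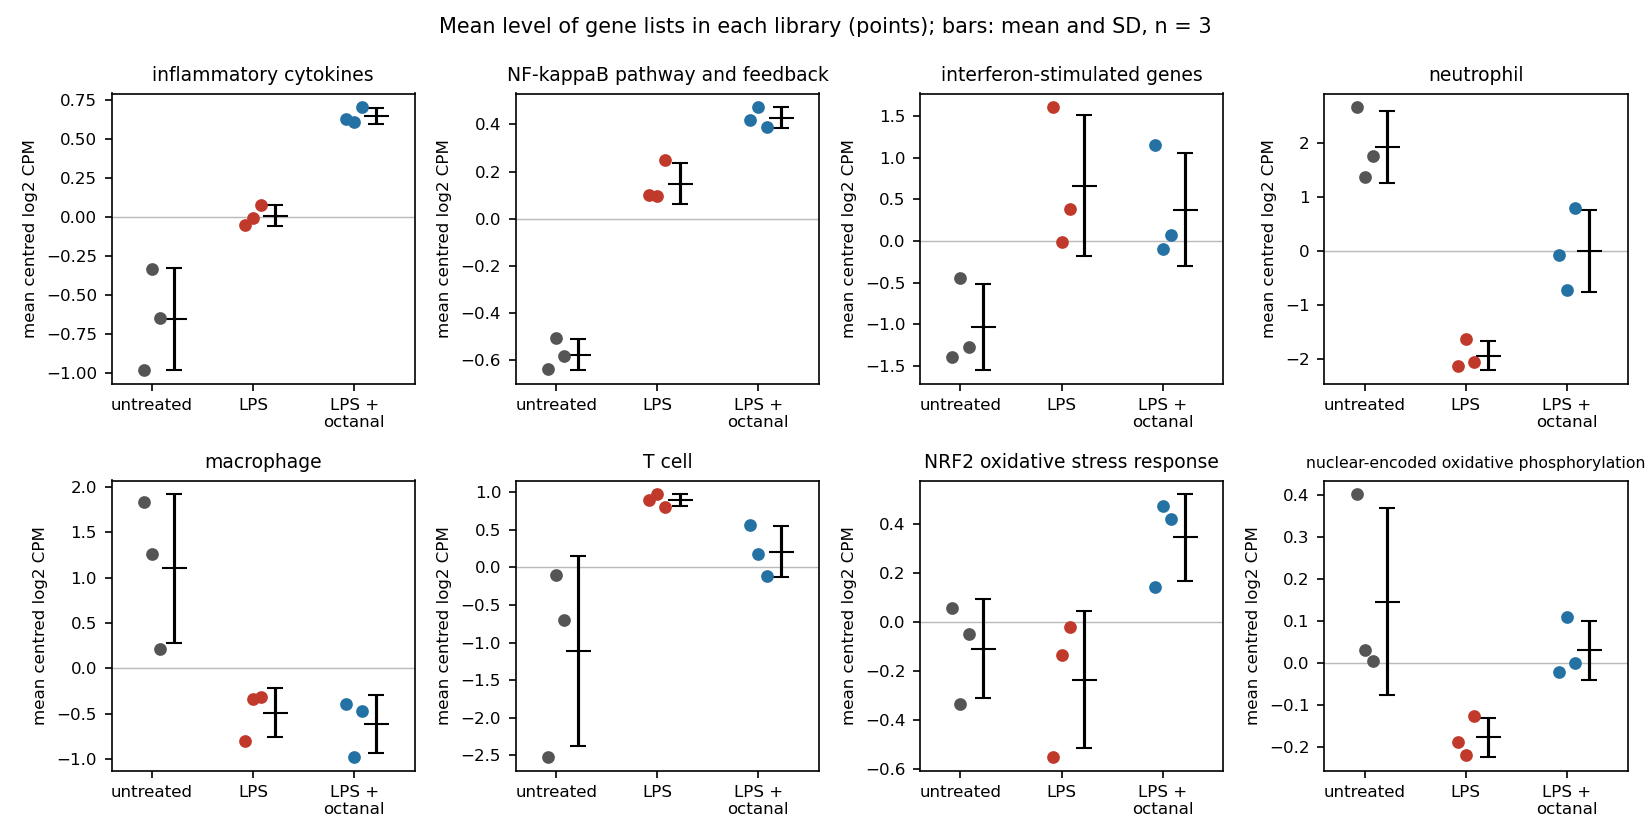
Mean log2 CPM of 8 gene lists, centred per gene, in each library (vertical axis) by group (horizontal axis), with a point per library and the mean and SD of 3 libraries beside them. The inflammatory cytokine list averages -0.65 in untreated, 0.01 in LPS and 0.65 in LPS with octanal libraries, and the neutrophil list 1.93, -1.93 and 0.00.

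LPS with octanal against LPS asks what octanal, the Olfr2 ligand, adds to LPS priming, and the labels do not say that the time in culture was equal. By edgeR 0 of 15447 genes were called. The lowest adjusted p was 0.051, shared by 47 genes, and 3450 genes had an unadjusted p under 0.05 (2108 higher and 1342 lower), against 772 by chance. The DESeq2 Wald test called 1614 genes (81.5% higher), limma-voom 0 and its fit with a sample weight per group 1750 (66.7% higher), and edgeR on the 6 libraries of both groups alone called 1380 (68.5% higher). Of the genes that shared the lowest adjusted p, chosen after their values were seen, Wfdc21 stood at 30.8 ± 3.17 CPM in LPS and 123 ± 35.8 in LPS with octanal libraries (log2 fold change 1.99) and Trem1, an amplifier of myeloid inflammation, at 5.44 ± 1.73 and 29.4 ± 8.61 (2.43). Sema4a stood at 46.7 ± 7.18 and 116 ± 14.5 (1.31), and Crip1 at 24.5 ± 4.54 and 10.4 ± 1.05 (-1.23). In untreated libraries Wfdc21 averaged 57.6, Trem1 47.0, Sema4a 162 and Crip1 9.60 CPM. With octanal, Trem1, Sema4a and Crip1 thus lay between the untreated and LPS means, and Wfdc21 lay above both. The edgeR count was 279 without a filter (97.1% higher), 346 with a filter at 10 CPM (93.6%) and 118 without NewGene loci (96.6%). It was 109 without untreated replicate 1 (95.4%), 527 without untreated replicate 2 (86.3%), 584 without LPS with octanal replicate 1 (83.2%) and 3, all higher, without LPS with octanal replicate 2. With DESeq2 size factors or a replicate block it stayed at 0. The count was also 0 without untreated replicate 3, without each LPS replicate and without LPS with octanal replicate 3. Limma-trend on log2 FPKM called 0 as well.

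Of 43 gene lists 17 passed by camera with the preset correlation, 7 by fry and 0 by camera with an estimated correlation. The list of 15 neutrophil markers was higher in LPS with octanal libraries (15 with a positive change, median log2 fold change 1.95, camera adjusted p = 4.3e-09, adjusted p = 0.45 with an estimated correlation), with 0 called over all genes and 11 adjusted over the list alone. S100a8 stood at 744 ± 101 and 2769 ± 775 CPM (log2 fold change 1.90) and Camp at 36.2 ± 3.28 and 233 ± 124 (2.68). The inflammatory cytokine list was higher by camera, with 14 of 18 changes positive (median 0.77, camera adjusted p = 7.3e-04, adjusted p = 0.22 with an estimated correlation, 9 adjusted over the list alone), with Tnf at 120 ± 18.9 and 279 ± 83.5 CPM and Ebi3 at 60.8 ± 14.0 and 153 ± 38.2. The NF-kappaB list was higher too, with 19 of 24 positive (median 0.21, camera adjusted p = 0.0016, adjusted p = 0.29 with an estimated correlation, 9 adjusted over the list alone). So were the lists of Toll-like receptor signalling (21 of 25 positive, median 0.53, camera adjusted p = 1.1e-04, adjusted p = 0.45 with an estimated correlation, 9 adjusted over the list alone) and of the inflammasome (13 of 17 positive, median 0.59, camera adjusted p = 9.3e-04, adjusted p = 0.29 with an estimated correlation, 4 higher and 1 lower adjusted over the list alone). Of those, Nfkbiz had a log2 fold change of 0.71, Tlr4 of 1.27 and Gsdmd, the pore-forming protein of pyroptosis, of 0.66. In untreated, LPS and LPS with octanal libraries, the mean centred log2 CPM of the Toll-like receptor list was 0.26, -0.34 and 0.08. That of the neutrophil list was 1.93, -1.93 and 0.00, so both lay between untreated and LPS with octanal. Highest with octanal were the cytokine (-0.65, 0.01 and 0.65), NF-kappaB (-0.58, 0.15 and 0.43) and inflammasome lists (0.02, -0.26 and 0.24).

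With 0 members called by edgeR in the fit of all 9 libraries in any list of this paragraph, directions are those of camera. The edgeR fit of the 6 libraries of both groups alone did call members of several of these lists. The NRF2 oxidative stress list was higher, with 23 of 23 changes positive (median 0.60, camera adjusted p = 7.2e-08, adjusted p = 0.58 with an estimated correlation), 13 of them adjusted over the list alone, with the quinone reductase gene Nqo1 at 34.2 ± 4.60 and 55.0 ± 2.31 CPM. The list of cholesterol synthesis and efflux was higher, with 22 of 26 positive (median 0.58, camera adjusted p = 1.1e-06, adjusted p = 0.45 with an estimated correlation), 16 higher and 1 lower adjusted over the list alone, with Idi1 at 0.92 and Pmvk at 0.68. The glycolysis list was higher, with 25 of 29 positive (median 0.51, camera adjusted p = 1.7e-05, adjusted p = 0.58 with an estimated correlation, 12 higher and 2 lower adjusted over the list alone), with the transporter gene Slc2a6 at 1.30. The remodelling list was higher, with 18 of 23 positive (median 0.84, camera adjusted p = 2.3e-04, adjusted p = 0.45 with an estimated correlation, 7 adjusted over the list alone), with Gpnmb at 1.80. The list of nuclear genes of oxidative phosphorylation was higher, with 61 of 76 positive (median 0.20, camera adjusted p = 4.2e-05, adjusted p = 0.70 with an estimated correlation). The list of mitochondrially encoded genes was lower, with 13 of 13 negative (median -0.87, camera adjusted p = 7.4e-05, adjusted p = 0.58 with an estimated correlation), and without LPS replicate 2 their mean change went from -0.74 to -0.47. Of both lists 0 members passed when adjusted over the list alone. The cell cycle list was higher by camera, but 13 of its 34 changes were negative (median 0.36, camera adjusted p = 0.032, adjusted p = 0.74 with an estimated correlation, 13 higher and 3 lower adjusted over the list alone), and without LPS with octanal replicate 3 their mean change went from 0.43 to 0.28. Lower were the lists of ribosomal protein genes (44 of 45 negative, median -0.39, camera adjusted p = 4.0e-12, adjusted p = 0.58 with an estimated correlation, 26 adjusted over the list alone) and heat shock genes (14 of 15 negative, median -0.36, camera adjusted p = 7.3e-04, adjusted p = 0.58 with an estimated correlation, 6 adjusted over the list alone). The MHC class II list was lower as well, with 12 of 15 negative (median -0.48, camera adjusted p = 0.036, adjusted p = 0.59 with an estimated correlation, 0 adjusted over the list alone). Against that direction, the edgeR fit of the 6 libraries of both groups called 2 of its members higher and 0 lower. The lists of T cell markers (13 of 13 negative, median -0.69, camera adjusted p = 0.033, adjusted p = 0.74 with an estimated correlation) and B cell markers (12 of 12 negative, median -0.77, camera adjusted p = 0.018, adjusted p = 0.70 with an estimated correlation) were lower, with 0 adjusted over the list alone. The lists of mitochondrial fission (median -0.10, camera adjusted p = 0.43), fusion (median 0.04, camera adjusted p = 0.81) and mitophagy (median 0.15, camera adjusted p = 0.072) did not pass. In the fit of all 9 libraries 0 of their members were called, also when adjusted over the list alone. The edgeR fit of the 6 libraries of both groups called 1 mitophagy gene, which was lower.

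Most genes called in LPS against untreated lay between both groups in LPS with octanal libraries: 2105 of 2353 genes that had risen (89.5%) and 2318 of 2719 that had fallen (85.3%). Genes picked for their change in LPS tend to lie between by chance. By the signs of the fitted changes the shares were 89.8% and 86.0%, against 58.7 to 62.3% and 55.5 to 60.2% for as many genes of lowest p in simulated data without any change. Of those that had risen, 791 were lower and 70 higher in LPS with octanal than in LPS at an unadjusted p under 0.05. Of those that had fallen, 1360 were higher and 4 lower, with 0 called by edgeR in each class. The DESeq2 Wald test called 5960 genes in LPS against untreated. Of those, it called 216 risen genes lower and 998 fallen genes higher in LPS with octanal against LPS. As both comparisons use the LPS libraries, chance links them. At an unadjusted p under 0.05 in both, 956 genes were higher in LPS and then lower, against 67.2 in simulated data without any change and 299 for independent lists. Another 1532 were lower and then higher, against 103 and 482. Higher in both were 81, against 1.15 and 469, and lower in both 8, against 1.30 and 307. The covariance of the log2 fold changes was -0.51, against -0.11 in the simulations. Genes are not independent replicates. The simulations share the LPS libraries too, but with genes drawn independently and the same spread in all groups. Part of the excess may for that reason still come from the shared libraries.

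LPS with octanal against untreated covers the whole treatment. Of the fixed lists, 15 of 24 NF-kappaB genes, 7 of 18 cytokines, 6 of 16 chemokines and 6 of 23 NRF2 genes rose. In turn 9 of 15 macrophage, 5 of 6 eosinophil, 5 of 12 B cell and 8 of 26 fatty acid oxidation genes fell, and with an estimated correlation only the NF-kappaB list passed. Tnf rose from 37.3 ± 8.92 to 279 ± 83.5 CPM (log2 fold change 2.91, SE 0.267, adjusted p = 0.0013), and the NF-kappaB inhibitor gene Nfkbia from 173 ± 4.62 to 470 ± 67.0 (1.44, SE 0.122, adjusted p = 8.0e-04). Apoe fell from 739 ± 267 to 134 ± 15.8 CPM (-2.46, SE 0.294, adjusted p = 0.0033). By edgeR 1339 genes were called, of which 407 rose and 932 fell, and 846 changed at least 2-fold (200 up and 646 down).

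The 12 largest rises were those of Csf3 (log2 fold change 7.59, SE 0.942), Cxcl2 (4.42), Il10 (4.14), Cxcl1 (4.08), Gpr84 (3.43), Mmp2 (3.38), Mfsd4a (3.08), the formyl peptide receptor gene Fpr1 (2.98), Ccl3 (2.94), Tnf and Tnfrsf8 (2.88). The last was Irak3 (2.83), a negative regulator of Toll-like receptor signalling. Among the 12 largest falls were those of Ly6c2 (-7.30), Chil4 (-4.61), Retnlg (-4.28), Amer2 (-4.27), Lrg1 (-4.01), Mertk (-3.95), Ltf (-3.90), Pi16 (-3.83), Trem2 (-3.79), Cd5l (-3.77) and Asprv1 (-3.73). Ly6c2 has the near-identical copy Ly6c1 and was at 2.82 CPM in untreated replicate 2, against 168 and 249 in the others of that group. Csf3 was at 0.360 CPM in untreated replicate 2 and had 0 counts in untreated replicates 1 and 3, so its fold rests on that library and has no upper limit without it (6.94 without untreated replicate 1). Without untreated replicate 2, Il10 went to 5.14 and Ly6c2 to -7.89. Without LPS with octanal replicate 3, Amer2 went to -6.44, Ltf to -5.11, Retnlg to -4.90, Lrg1 to -4.88, Pi16 to -4.70 and Asprv1 to -4.32. Lrg1 went to -3.39 and Cd5l to -3.05 without untreated replicate 1, and Chil4 to -3.78 and Ly6c2 to -6.57 without untreated replicate 3. Ly6c2 lost its call without each of untreated replicates 1 and 3 and the LPS with octanal replicates, and Amer2 without each of untreated replicates 1 and 3, LPS replicates 2 and 3, and LPS with octanal replicates 1 and 2. Ltf lost its call without untreated replicate 1 or LPS with octanal replicate 1, Lrg1 without LPS with octanal replicate 1 or 2, and Tnfrsf8, Chil4, Trem2 and Cd5l without LPS with octanal replicate 2.

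Of 24 NF-kappaB genes 15 rose (18 when adjusted over the list alone; camera adjusted p = 2.6e-14), and this call held with an estimated correlation (adjusted p = 0.040). Of 18 inflammatory cytokines 7 rose and Il18 fell (-1.51) (8 and 2 when adjusted over the list alone; camera adjusted p = 3.8e-04, adjusted p = 0.22 with an estimated correlation). Of 16 chemokines 6 rose and Ccl6 fell (-1.99) (8 and 1 when adjusted over the list alone; camera adjusted p = 7.3e-04, adjusted p = 0.29 with an estimated correlation). Of 32 interferon-stimulated genes 4 rose, Oasl1 (2.71), Gbp3 (1.63), Gbp5 (1.43) and Isg15 (2.13), also when adjusted over the list alone (camera adjusted p = 3.4e-08, adjusted p = 0.62 with an estimated correlation). These 4 calls were lost without untreated replicate 1, untreated replicate 3, LPS replicate 3, or LPS with octanal replicate 1 or 2, and at least 1 of them without each other library. Oasl1 went to 3.43 without untreated replicate 2. For this list LPS with octanal replicate 1 stood apart, at a mean centred log2 CPM of 1.15 against -0.10 and 0.07 in replicates 2 and 3. Of 23 NRF2 genes 6 rose (9 when adjusted over the list alone), such as Nqo1 (1.36), Abcc1 (1.12) and Gsr (1.09) (camera adjusted p = 9.7e-05, adjusted p = 0.64 with an estimated correlation). Of 24 apoptosis and p53 target genes 3 rose, Fas (2.72), Bcl2a1d (0.83) and Bax (0.72), against 11 up and 2 down when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.45 with an estimated correlation).

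Of 15 macrophage markers 9 fell (11 when adjusted over the list alone), and Adgre1, which encodes F4/80, rose (1.40) (camera adjusted p = 1.1e-04, adjusted p = 0.58 with an estimated correlation). Of 15 neutrophil markers 5 fell (11 when adjusted over the list alone), such as Cxcr2 (-3.44, and -4.45 without LPS with octanal replicate 3) (camera adjusted p = 5.9e-05, adjusted p = 0.58 with an estimated correlation). Of 6 eosinophil markers 5 fell (6 when adjusted over the list alone; camera adjusted p = 6.3e-06, adjusted p = 0.28 with an estimated correlation). Of 13 classical monocyte markers 6 fell (7 when adjusted over the list alone) and Cd14 rose (1.23) (camera adjusted p = 0.016, adjusted p = 0.58 with an estimated correlation). Of 12 B cell markers 5 fell (11 when adjusted over the list alone), such as Cd22 (-1.42) (camera adjusted p = 0.0013, adjusted p = 0.66 with an estimated correlation). Of 26 fatty acid oxidation genes 8 fell (10 when adjusted over the list alone), such as Pparg (-2.41) and Cpt1a (-0.57) (camera adjusted p = 3.9e-06, adjusted p = 0.45 with an estimated correlation). Of 34 cell cycle genes 11 fell (21 when adjusted over the list alone), such as Rrm2 (-2.08) (camera adjusted p = 4.2e-08, adjusted p = 0.58 with an estimated correlation). Of 23 remodelling genes 10 fell (15 down and 1 up when adjusted over the list alone), such as Timp2 (-1.41) (camera adjusted p = 3.3e-06, adjusted p = 0.31 with an estimated correlation). T cell markers stood higher by camera (median 1.08, adjusted p = 2.5e-04, adjusted p = 0.66 with an estimated correlation) with 0 of 13 called, also when adjusted over the list alone. Of 14 fission genes Mtfr2 fell (-0.89) and of 18 mitophagy genes Sqstm1 rose (1.19), both also when adjusted over the list alone, while 0 of 14 fusion genes were called (camera adjusted p = 0.33, 0.33 and 0.94). Without untreated replicate 1 the mean change of the T cell list went from 1.32 to 0.61. In all, 25 of 43 lists passed with the preset correlation, 1 with an estimated one and 12 by fry.

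Of the 407 genes that rose here 285 had also risen in LPS against untreated, and of the 932 that fell 843 had also fallen, against 62.0 and 164 for independent lists. The covariance of the log2 fold changes was 0.80, against 0.11 in simulated data. The simulated data share the untreated libraries too, but with genes drawn independently and the same spread in all groups. Part of the excess may for that reason still come from the shared untreated libraries. The called count was 623 without untreated replicate 1 and 2137 without untreated replicate 2. It was 810 without LPS replicate 2, 787 without LPS replicate 3, and 789, 298 and 670 without LPS with octanal replicates 1, 2 and 3. The 2-fold count was 407 and 1284 without untreated replicates 1 and 2, and 536, 255 and 556 without LPS with octanal replicates 1, 2 and 3. Without LPS with octanal replicate 2 the calls of Adgre1, Cd14, Cd22, Rrm2, Bax, Bcl2a1d, Gsr, Abcc1, Mtfr2 and Sqstm1 were lost, most of them also without other libraries. The called count was 2621 by the DESeq2 Wald test and 404 with only the 6 libraries compared.

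**Figure D3:**
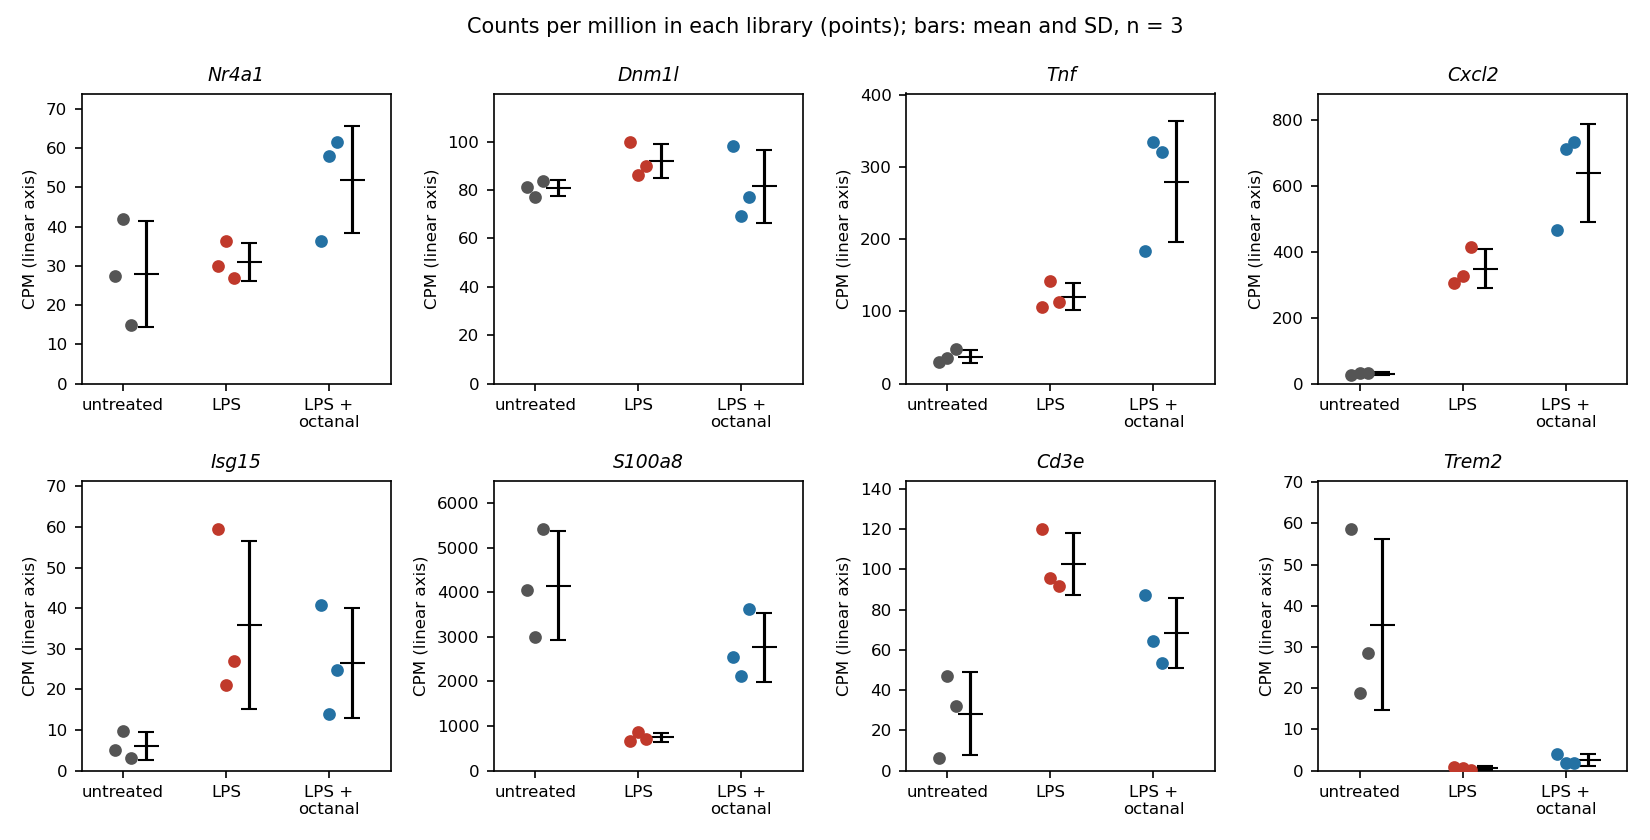
CPM of 8 genes in each library (vertical axis, linear and from 0) by group (horizontal axis), with a point per library and the mean and SD of 3 libraries beside them. Nr4a1 averages 28.0, 31.0 and 52.0 CPM and S100a8 4155, 744 and 2769 CPM in untreated, LPS and LPS with octanal libraries.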

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

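The fit without the NewGene loci and limma-voom with a sample weight per group were the tests chosen only after the result was seen. Counts of called genes are given for LPS against untreated (LU), LPS with octanal against LPS (OL) and LPS with octanal against untreated (OU), with those of at least 2-fold in parentheses, and where no construction is named the cause was not tested. The DESeq2 Wald test gave 1614 (620) in OL and 2621 (1464) in OU. It called 216 genes raised by LPS as lower and 998 lowered by LPS as higher in OL. Here and below, genes raised or lowered by LPS are those that the same fit called in LU. Without the filter OL gave 279 (211), with 4 and 226 such genes. The filter at a mean of 10 CPM, which tests fewer genes, gave 1283 at 2-fold in LU, 346 (192) in OL with 17 and 269 such genes, 501 at 2-fold in OU, and -0.021 for Dnm1l in OU. Fits of the 6 libraries compared gave 1380 (459) in OL, with 240 and 661 such genes, and 404 (342) in OU. Log2 FPKM gave 1528 at 2-fold in LU and 532 in OU. Without NewGene loci OL gave 118 (87), with 2 and 90 such genes, and with group weights 1750 (492), with 431 and 776. For gene lists, the estimated correlation left 0, 0 and 1 in LU, OL and OU, and fry gave 7 in OL and 12 in OU. As signed -log10 of adjusted p, the fusion list turned to 0.0015 in the 6 libraries and 0.016 without NewGene loci in OU, and to 0.016 in LU and -0.028 in OL by FPKM, and mitophagy turned to 0.016 in LU by FPKM. Leaving out each library gave, in LU, 2387 to 5658 (1520 to 3176) genes, 18 to 22 lists, Nr4a1 at -0.16 to 0.53 and Dnm1l at 0.11 to 0.21. In OL it gave 0 to 584 (0 to 339) genes, 16 to 21 lists, Nr4a1 at 0.63 to 0.98, Dnm1l at -0.29 to -0.05, and 0 to 65 and 0 to 396 genes that went back. In OU it gave 298 to 2137 (255 to 1284) genes, 21 to 25 lists, Nr4a1 at 0.62 to 1.30 and Dnm1l at -0.13 to 0.11. The fusion list ranged from -0.340 to 0.0346 in LU, -0.0570 to 0.391 in OL and -0.327 to 0.267 in OU, mitophagy from -0.299 to 0.125 in LU, and oxidative phosphorylation from -2.68 to 0.138 in OU. A replicate block gave 4257 (2120), 0 and 923 (590) genes and 20, 19 and 24 lists. Across all genes the replicate numbers showed no clear pairing. Of 9 same-number pairs 1 correlated above 0.1, and 2 of 9 libraries correlated best with their own number. With 3 libraries per group such correlations cannot exclude a pairing, on which the labels are silent. The interferon-stimulated list was highest in replicate 1 of the LPS group (mean centred log2 CPM 1.61) and of the LPS with octanal group (1.15). Without untreated replicate 2, Nr4a1 passed in OU (1.30, adjusted p = 0.035). Of 109, 87 and 125 gene values followed in LU, OL and OU, with Nr4a1 and Dnm1l left aside, 1893 of 2048, 1305 of 1649 and 2030 of 2338 alternatives kept direction and side of the threshold, and 0 turned. The DESeq2 Wald test gives no camera value, and alternatives meant for series with FPKM alone were not run because counts are held.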

Other observations

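In this part, the tests on cell shares, the background of overlapping genes, the octanal marker values, the list means without a library, the simulated share of genes between groups and the choice of Aass were chosen only after the result was seen. 3 further lists passed camera in LPS against untreated cells with the preset correlation and not with an estimated one. Of 18 alternative activation genes 7 fell, such as Chil3 (log2 fold change -5.13), Stab1 (-1.90) and Clec10a (-3.89), and 2 rose, such as Il10 (3.38), with 10 and 2 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.30 with an estimated correlation). Chil3 has the near-identical copy Chil4 and is uncertain. Without untreated replicate 3 Clec10a went to -3.22, and without untreated replicate 2 Il10 to 4.36. Of 26 genes of cholesterol synthesis and efflux 6 fell, such as Abcg1 (-1.02) and Nr1h3 (-1.25), and Mylip rose (0.77), also when adjusted over the list alone (camera adjusted p = 0.047, adjusted p = 0.70 with an estimated correlation). Of 5 basophil and mast cell markers 2 fell, Hdc (-5.03) and Prss34 (-3.37), also when adjusted over the list alone (camera adjusted p = 0.049, adjusted p = 0.58 with an estimated correlation). Prss34 lost its call without each of untreated replicates 1 and 3 (-2.60), the LPS replicates (-4.25 without replicate 3) and LPS with octanal replicates 2 and 3, and Nr1h3 was not called without LPS replicate 1.

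In LPS with octanal against untreated, 4 of 18 alternative activation genes fell, such as Irf4 (-1.82), and Il10 rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.36 with an estimated correlation). Of 26 cholesterol genes Cyp51 rose (0.69) and 3 fell, such as Abcg1 (-1.17), against 10 and 3 adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.68 with an estimated correlation). The mean change of the cholesterol list was 0.16, so it stood higher. Of 6 plasma cell markers 2 fell, Sdc1 (-1.83) and Irf4, also when adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.58 with an estimated correlation). Of 5 basophil and mast cell markers Hdc fell (-2.62), also when adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.58 with an estimated correlation). With 0 members called by edgeR, also when adjusted over the list alone, NK cell markers (median 0.94, camera adjusted p = 0.010, adjusted p = 0.58 with an estimated correlation), ribosomal protein genes (0.20, 9.3e-05, adjusted p = 0.70 with an estimated correlation) and MHC class I genes (0.33, 0.036, adjusted p = 0.74 with an estimated correlation) stood higher. Likewise erythroid (-0.89, 0.016, adjusted p = 0.67 with an estimated correlation), megakaryocyte (-0.79, 0.018, adjusted p = 0.70 with an estimated correlation) and oxidative phosphorylation genes (-0.13, 0.049, adjusted p = 0.84 with an estimated correlation) stood lower, the last with a turned sign (0.138 as signed -log10 of adjusted p) without untreated replicate 1. Without LPS with octanal replicate 2, the calls of Cyp51, Abcg1, Irf4 and Hdc were lost. Cyp51 also lost its call without each other library but untreated replicate 3 and LPS with octanal replicate 1, and Hdc without untreated replicate 1 or LPS with octanal replicate 1. Some mean changes in this comparison moved by over 1.5 times without a library. Without untreated replicate 1, NK cell markers went from 0.84 to 0.48 and oxidative phosphorylation from -0.12 to 0.01, the latter to -0.19 without untreated replicate 3. Ribosomal protein genes went from 0.22 to 0.34 and 0.13 without untreated replicates 2 and 3, and cholesterol genes from 0.16 to 0.09 without untreated replicate 2. MHC class I genes went from 0.26 to 0.08 without LPS with octanal replicate 1, and megakaryocyte markers from -0.94 to -1.48 and -0.48 without LPS with octanal replicates 1 and 2.

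The enzyme gene Aass had 3755 counts over the LPS, 2956 over the untreated and 0 over the LPS with octanal libraries. That is at least 1276-fold lower than in LPS (adjusted p = 0.079) and at least 1041-fold lower than in untreated (adjusted p = 0.046). Untreated replicate 2 also had 0 counts of Aass, so the groups overlap, and in LPS with octanal against untreated the call was lost without each of the 8 other libraries. From LPS to LPS with octanal, the mean log2 change was -0.69 (SE 0.205) for T cell, -0.64 (SE 0.123) for B cell, -0.37 (SE 0.206) for NK cell and -0.38 (SE 0.262) for dendritic cell markers. The mitophagy list in LPS with octanal against untreated had a median log2 fold change of -0.01, a mean of 0.13 and a camera test pointing up (adjusted p = 0.33).

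Neutrophil markers fell and T cell markers rose in LPS against untreated. A lower share of a single main cell type would raise the markers of every other type alike. T cell markers exceeded eosinophil markers by 4.94 (SE 1.00) on the log2 scale. This pair was picked after the values were seen, and eosinophils are granulocytes like neutrophils. Loss of a granulocyte fraction could lower both lists, so this difference does not decide it. Without each library in turn this difference was 3.97 (SE 0.355, without untreated replicate 1) to 5.58 (SE 1.31, without untreated replicate 2), while T cell against B cell markers alone (2.50, SE 0.987) fell short of 2 standard errors without untreated replicate 2 (2.68, SE 1.67) and went to 1.57 without untreated replicate 1. Besides neutrophils, eosinophils had the largest difference to T cell markers of the types compared. It was 3.59 (SE 1.10) for macrophage markers, and 0.80 (SE 0.407) for NK cell markers, which is under 2 standard errors. The macrophage difference stayed above 2 standard errors without each library in turn (lowest 2.31, without untreated replicate 2), so the lists did not all move alike. For loss of a granulocyte population, the SD of the neutrophil markers' changes was 2.96 times their median standard error, which does not decide because remaining cells may express some of these markers. Loss of a granulocyte fraction, changes in the shares of several cell types and a response to LPS within the cells stay open.

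By edgeR 0 genes were called in LPS with octanal against LPS in the fit of all 9 libraries, with 3450 at an unadjusted p under 0.05. The fit of the 6 libraries of both groups called 1380, and a prediction written beforehand had asked for at least 100 if the spread of the untreated libraries widens the shared variance. The prediction was met, and the median SD between replicates was 0.31 in untreated against 0.17 and 0.22 in the other groups. Other fits were mixed on the untreated spread. Without untreated replicates 1, 2 and 3, each left out alone, edgeR called 109, 527 and 0 genes. With all untreated libraries kept, it called 584 without LPS with octanal replicate 1. The DESeq2 Wald test called 1614 and limma-voom 0. Limma-voom with a sample weight per group, which lets the spread differ between groups, called 1750, and that goes with the prediction. Why the fit of all 9 libraries called 0 stays open. Octanal and a longer time in culture cannot be separated by the labels, and no test here addresses that.

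There were 45 genes with a known position whose highest library of a group was above 10 CPM and over 15 times its lowest, of which 5 were called in LPS against untreated and 2 in LPS with octanal against untreated. Genotype differences between animals would make neighbouring genes vary together, and 71.2% of random draws had a lower correlation with neighbours, which does not decide it. Reads moved between overlapping gene models would put these genes among overlapping ones, and 53.3% overlap another gene, which met the prediction written beforehand. Yet 54.1% of 1000 random tested genes overlap another gene, so that test is void. No other biological explanation was tested.

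With 10 splits of 6 libraries the share of splits with a result as large cannot go below 0.1. In LPS against untreated, 1 split gave as many genes (5072, highest other 0), 1 as many at 2-fold (2465, highest other 0) and 2 as many lists (20, highest other 22). In LPS with octanal against LPS these were 10 (0, highest other 2), 10 (0, highest other 2) and 2 (17, highest other 17). In LPS with octanal against untreated they were 1 (1339, highest other 1), 1 (846, highest other 1) and 1 (25, highest other 17).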
